A study of Mus musculus with 10 samples.

How the data were processed

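Jejunal RNA of 10 male mice at postnatal day 30 was measured on 10 Affymetrix mouse 430A arrays, 5 labelled Klf9 knockout and 5 labelled wild type. Per the labels' protocols, total RNA was converted to biotin-labelled cRNA. Per the series' design text, 1 array was hybridised per animal and images were quantified with MAS 5.0. The labelling protocol also speaks of RNA pools, so that the account of 1 animal per array rests on the design text. One characteristic of knockout replicate 1 names both genotypes, and its title, which gives knockout, was used. The deposited values are linear signal intensities per probe set, never below 0, which the authors had scaled so that every array has the same 2% trimmed mean of about 500. Other deposited files record the settings of washing and scanning. From these only the fluidics module and the hybridization time of each array were used. Wash runs are not named there and were told apart by gaps between these times, giving 3 wash runs and 4 modules. Detection calls were not used here.

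Each array was scaled again to a 2% trimmed mean of 500, which moved values very little, and log2(signal + 50) was taken. A fold change is therefore on the scale of signal plus 50 and understates the change of dim genes. Control probe sets (64 of 22690, with the only empty value) were left out of the tests. Probe sets were kept if their mean scaled signal over all 10 arrays exceeded the 40th percentile (123), with the 7 Klf9 probe sets always kept, which left 13579. The number of arrays, 5 in each group, limits the precision.

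Probe sets were named from the platform annotation. Outside the controls, 20380 had 1 symbol, 691 several and 1555 none. Of those with 1 symbol, 20351 were matched by gene ID to a RefSeq gene table of another source and took its symbol, whether or not it differed. That table was used only for names, chromosomes and neighbourhood. Probe sets with several symbols were not named in the rule below. For single genes, the tested probe set with the highest mean over all arrays stood for the gene (8290 genes). Where probe sets of a gene differ, the table of all probe sets holds each of them.

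The groups were compared in limma 3.58.1 (R 4.3.3) with lmFit on 2 groups and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. SEs are limma's moderated ones, and SDs are over the 5 arrays of a group. A total of 34 gene lists of cell types, processes, regions and tissues that may be carried along were fixed before the data were examined, and the 31 with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 31. The SE of a list's mean is over the arrays' list means. The named genes were fixed by rule before the data were examined: all Klf9 probe sets, up to 15 genes in each direction past the threshold by size, and where fewer than 10 passed the genes of lowest p up to 10, then 2 to 4 genes of lowest p in each list. Other genes named were chosen after their values were seen. Chromosome 19 was tested with Fisher's exact test, and single values and list means with exact permutation of the 252 ways to draw 5 of 10 arrays.

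The limma step was tested on 13579 simulated probe sets with the real means and SDs. It called 93 of 100 changed 2-fold and 50 of 100 changed 1.5-fold in the right direction, with 6 false calls. The camera step on 8290 simulated genes called the 1 list shifted by -0.4 and 0 of 30 others, in data without correlation between genes. A list keeps its direction under an alternative if the sign of its mean holds, a rule set after the values were seen in place of camera's direction. Alternatives tried were offsets of 1, 16 and 100, no filter and a 60th percentile, values as deposited, quantile and cyclic loess normalization, eBayes without trend or robust, array weights, replicate number, wash run or module as a block, each array left out, an estimated correlation and the mean over a gene's probe sets for lists, and a 20 Mb window around Klf9. Leaving out both arrays labelled replicate 1, exact permutation of list means, the antimicrobial list without its 2 genes of lowest p and the unadjusted threshold on chromosome 19 were added after seeing the data.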

Results

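Klf9 (Kruppel-like factor 9) is a zinc finger transcription factor of the KLF and Sp family that responds to glucocorticoid and thyroid hormones. RNA of the jejunum, the middle part of the small intestine, was profiled in male mice at postnatal day 30 on Affymetrix mouse 430A GeneChips, in which sets of short oligonucleotide probes each measure 1 transcript. Per the labels, 5 arrays came from animals lacking Klf9 and 5 from wild type animals. The design text gives 1 animal per array, although the labelling protocol speaks of RNA pools. The comparison asks which jejunal transcripts differ without Klf9, in a study of crypt cell proliferation and of cell migration along the villus. Each array held 22690 probe sets, and the median signal lay between 171 (knockout replicate 5) and 194 (knockout replicate 3) after the authors had scaled all arrays to a common mean. Array number, 5 in each group, limits the precision of every value.

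Klf9 itself was lower on the arrays labelled knockout, but not on all of them. The brightest of its 7 probe sets had a scaled signal of 549 ± 231 (SD, n = 5) on the arrays labelled knockout and 1024 ± 302 (SD, n = 5) on those labelled wild type, a log2 difference of -0.86 ± 0.25 (SE). The exact two-sided permutation test on the log2 values gave p = 0.0159, where 0.00794 is the smallest p that 5 against 5 allows. In limma the adjusted p was 0.466 over all probe sets tested and 0.0273 adjusted over the 7 Klf9 probe sets alone. The array labelled knockout replicate 1 had a Klf9 signal of 944, and the array labelled wild type replicate 1 had 551. The other arrays labelled knockout lay between 340 and 526, and the other arrays labelled wild type between 964 and 1320. The next brightest pair of probe sets had the same order for both arrays labelled replicate 1 (453 against 178, and 169 against 72.8), with log2 differences of -0.66 ± 0.29 and -0.62 ± 0.25 (SE). Klf9 thus goes against the label on 2 arrays, and every direction given here rests on labels that it contradicts there. Which part of the gene the mutation removes is not given in the sources used here, so a probe set outside that part would check nothing.

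**Figure D1:**
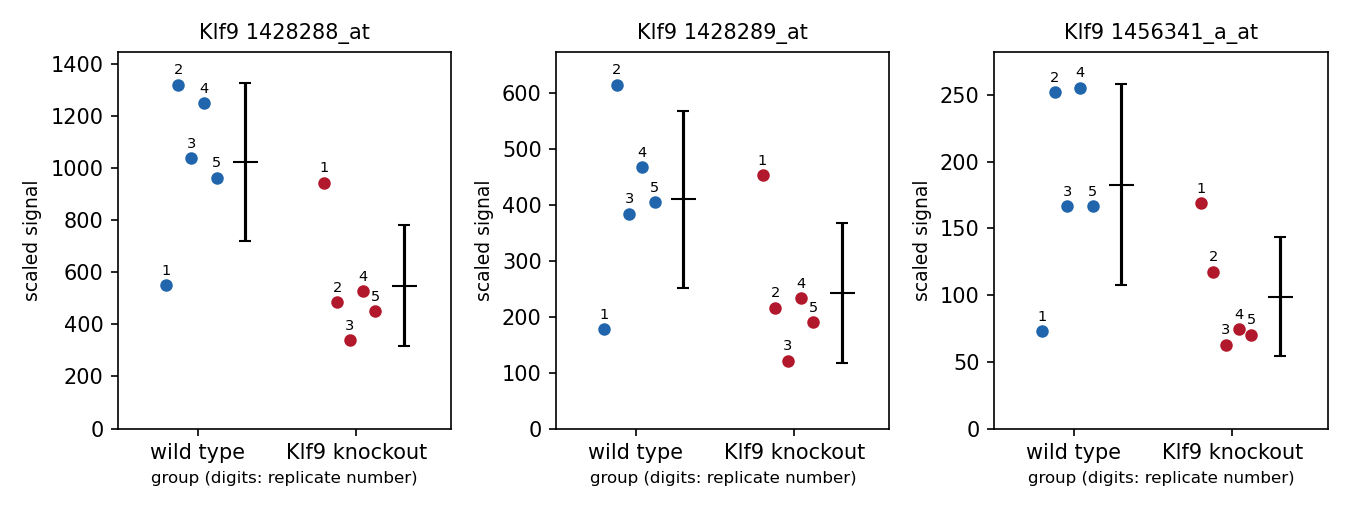
Scaled signal of the 3 brightest Klf9 probe sets (vertical axes, linear, arbitrary units) on each array by labelled group; points are arrays with their replicate numbers, and black bars are the mean and SD of 5 arrays. In the left panel knockout replicate 1 (944) lies close to the lowest of the other wild type arrays (964), and wild type replicate 1 (551) lies close to the highest of the other knockout arrays (526).

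No probe set passed the threshold between the labelled groups. Of 13579 probe sets tested with limma, 0 had an adjusted p under 0.05, and 1072 had an unadjusted p under 0.05, where 679 would have one with no difference at all. Of these 1072, 496 were higher and 576 lower on the arrays labelled knockout. The smallest adjusted p was 0.0795. On simulated arrays of the same spread, the same fit called 93 of 100 probe sets changed 2-fold and 50 of 100 changed 1.5-fold. These changes were planted together, in data without correlation between genes. The Benjamini-Hochberg cutoff on p eases as more probe sets change. With fewer real changes the cutoff is stricter, so these shares overstate what the fit would then find. Without both arrays labelled replicate 1, an alternative chosen after the Klf9 values were seen, 9 probe sets passed, and without knockout replicate 1, knockout replicate 5 or wild type replicate 1 alone, 5, 3 and 1 passed. The 9 were Klf9 (log2 -1.26), 2 probe sets of Stom (-1.25 and -1.36), Tppp3 (0.85), Tubb2a (1.15), 1 of Ceacam1 (-0.88) and 3 annotated to several genes each.

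Among single genes, the 10 higher ones with the lowest p on the arrays labelled knockout differed by 0.35 to 0.95 on the log2 scale, and none passed the threshold. Tppp3, a tubulin polymerization-promoting protein, was 1.69 times as high (log2 0.76 ± 0.11 SE; adjusted p = 0.0795), with log2 means of 9.06 ± 0.08 and 8.30 ± 0.18 (SD, n = 5). Tubb2a, a beta-tubulin, was 1.93 times as high (log2 0.95 ± 0.17 SE; adjusted p = 0.234), on a probe set that may also read related tubulins. Srf, the serum response factor that drives muscle and immediate early genes, differed by 0.40 ± 0.10 (SE). Egln3, a prolyl hydroxylase acting on hypoxia-inducible factor, differed by 0.55 ± 0.13, and Pfkl, a phosphofructokinase of glycolysis, by 0.46 ± 0.12. Anapc7, a subunit of the anaphase-promoting complex, differed by 0.50 ± 0.12, Colgalt1, a collagen galactosyltransferase, by 0.52 ± 0.12, and Ubqln4, a ubiquilin, by 0.47 ± 0.11. Ppt2, a lysosomal thioesterase, and Aldh1b1, a mitochondrial aldehyde dehydrogenase, differed by 0.42 ± 0.11 and 0.35 ± 0.09. For 9 of these 10 genes every array labelled knockout lay above every array labelled wild type. As the genes were picked by p on these same arrays, that separation is no separate evidence.

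The 10 lower genes with the lowest p differed by -0.44 to -2.24 on the log2 scale, and none passed. Saa1, serum amyloid A, had a log2 difference of -2.24 ± 0.55 (SE, adjusted p = 0.441), and of -1.41 ± 0.34 on another probe set. On the former, wild type replicates 3 to 5 were high (log2 10.9, 10.3 and 9.62). Wild type replicates 1 and 2 (7.53 and 7.92) lay near the arrays labelled knockout (6.39 to 7.77). Tifa, an adaptor of NF-kappa B signalling, differed by -1.02 ± 0.21, and Socs3, a suppressor of cytokine signalling, by -0.76 ± 0.16. Ptk6, a tyrosine kinase of differentiating epithelium, differed by -0.59 ± 0.12 (adjusted p = 0.382), and Net1, an exchange factor for RhoA, by -0.77 ± 0.17. Slc26a3, the chloride and bicarbonate exchanger of the brush border, differed by -0.44 ± 0.11, and Clca3a1, a calcium-activated chloride channel regulator, by -0.60 ± 0.15. Fbxo36, an F-box protein, differed by -0.65 ± 0.13, Kcna7, a potassium channel, by -0.97 ± 0.24, and Zfp36l1, which promotes messenger RNA decay, by -0.45 ± 0.12. The Socs3 and Clca3a1 probe sets may share signal with related sequences. For 5 of these 10 genes the groups did not overlap, and these too were picked by p on the same arrays. Over all tested probe sets 1.55% were without overlap, where chance gives 0.794% for 5 against 5. That share was not compared with other splits of the arrays.

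**Figure D2:**
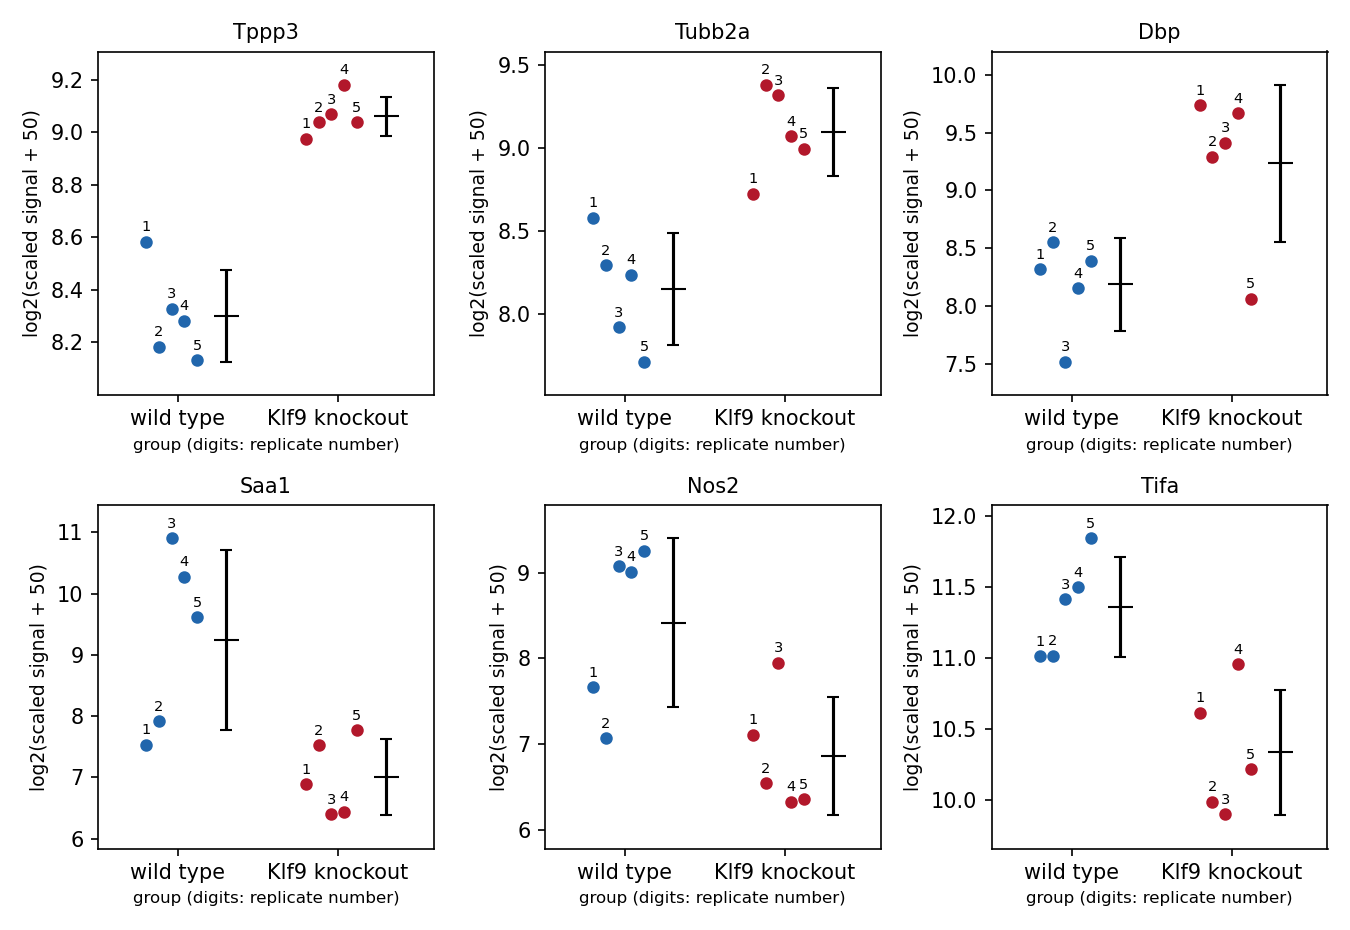
Level of 6 genes on each array, as log2(scaled signal + 50) on the vertical axes, by labelled group; points are arrays with their replicate numbers, and black bars are the mean and SD of 5 arrays. Tppp3 does not overlap between the groups, while Dbp is low on knockout replicate 5 (8.06) and at least 9.29 on the other arrays labelled knockout.

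The fluidics module of each array was recorded, and its wash run was inferred from gaps between the recorded hybridization times. Wash runs 1 and 2 each held 2 arrays of each label, run 3 held 1 of each, and only module 4 held both labels, with 1 knockout and 2 wild type arrays. Knockout replicate 5 was the knockout array of both run 3 and module 4. Values within run 3 and within module 4 share that array and are not separate checks. With the wash run as a block 0 probe sets passed and 1095 had an unadjusted p under 0.05, and with the module as a block 0 passed and 471 had. Within runs 1, 2 and 3, the brightest Klf9 probe set differed by -0.31, -1.33 and -1.02 on the log2 scale, and within module 4 by -1.41.

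The lists closest to the study's question, those of crypt proliferation and villus migration, did not pass the threshold as groups. Given the SEs of their means, a difference in either direction is not excluded. Of 32 measured proliferation genes 22 were higher and 10 lower on the arrays labelled knockout, with a mean log2 difference of 0.05 ± 0.17 (SE over arrays; camera adjusted p = 0.283). Bub1b, of the spindle checkpoint, and Cenpa, of the centromere, differed by 0.26 ± 0.14 and 0.21 ± 0.12. Without knockout replicate 1 or wild type replicate 3 that list passed, with adjusted p = 0.00288 and 0.0230, but without knockout replicate 3 or wild type replicate 1 its mean turned to -0.07 and -0.0013. The adjusted p was 0.812 with an estimated correlation, which was 0.675 between these genes. Crypt base stem cell genes were split, 6 higher and 6 lower, with a median of 0.01 opposite in sign to the mean (-0.01 ± 0.07; camera adjusted p = 0.562). Among them the stem cell receptor Lgr5 differed by -0.29 ± 0.13 and Igfbp4 by 0.46 ± 0.16. The 14 Wnt pathway genes had a mean difference of -0.07 ± 0.04 (camera adjusted p = 0.183), with the transcription factor Tcf7l2 at -0.27 ± 0.13 and the receptor Fzd7 at -0.20 ± 0.12.

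The homeobox factors Cdx1 and Cdx2, which set intestinal identity, were higher by 0.50 ± 0.14 and 0.44 ± 0.13 (SE). They were the 2 of 16 cell cycle inhibitors and differentiation regulators that passed when adjusted over the list alone (limma adjusted p = 0.0313 for both), and 0 passed over all probe sets. As a group that list had a mean of 0.04 ± 0.05 (camera adjusted p = 0.344). Of 26 genes of cell migration, adhesion and basement membrane, 13 were higher and 13 lower (mean -0.02 ± 0.05; camera adjusted p = 0.295). Ptk6 alone passed there when adjusted over the list alone (adjusted p = 0.00595), and the small GTPase Cdc42 differed by -0.36 ± 0.11.

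Genes of antimicrobial and inflammatory epithelium were lower on the arrays labelled knockout, 9 of 12 measured members, with a mean log2 difference of -0.48 ± 0.15 (SE over arrays) and a median of -0.20, and all 5 arrays labelled knockout lay below the wild type mean. The exact permutation test of the list mean gave p = 0.0159, and 0.492 adjusted over the lists. Saa1 and Nos2 carry the mean: without both, chosen after the values were seen, the other 10 genes differed by -0.20 ± 0.16 (SE, exact permutation p = 0.238). Like Saa1, Nos2 was high only on wild type replicates 3 to 5 (log2 9.07, 9.01 and 9.26). On wild type replicates 1 and 2 it was 7.66 and 7.07, within the range of the arrays labelled knockout (6.33 to 7.95). Wild type replicates 1 and 2 were in wash run 1, and replicates 3 to 5 in runs 2 and 3. Among the wild type arrays the high levels of Saa1 and Nos2 thus fall along the wash runs. The camera test with a preset correlation gave an adjusted p of 0.00134, and the adjusted p was 0.54 with an estimated correlation. Adjusted over the list alone 3 members passed and over all probe sets 0. These were Saa1, Nos2 (inducible nitric oxide synthase; -1.56 ± 0.42) and Reg3g (an antibacterial lectin; -0.49 ± 0.14), with adjusted p = 0.0147, 0.0148 and 0.0180 over the list. Reg3a, of the same lectin family, differed by -0.66 ± 0.29, and by -0.33 without knockout replicate 3. Within wash runs 1, 2 and 3 the list differed by -0.10, -0.79 and -0.62 and within module 4 by -0.40, and with the module as a block, where only 1 knockout array informs it, it no longer passed (adjusted p = 0.164).

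Markers of B and plasma cells were also lower, 10 of 11 measured genes, by a mean of -0.43 ± 0.23 (SE over arrays; median -0.32) and on 4 of 5 arrays labelled knockout. This list had the lowest p with a preset correlation (camera adjusted p = 0.000321), and the adjusted p was 0.54 with an estimated correlation. None of its members passed, over all probe sets or adjusted over the list alone. The immunoglobulin genes Ighm and Iglv1 differed by -0.47 ± 0.17 and -1.10 ± 0.57 (Iglv1 by -0.60 without knockout replicate 3), the B cell kinase Blk by -0.33 ± 0.15 and Derl3, of the secretory pathway, by -0.26 ± 0.12. Within wash runs 1, 2 and 3 the list differed by 0.16, -0.96 and -0.57, so the direction was not shared by run 1, and within module 4 it differed by -0.36. Without knockout replicate 3 it differed by -0.26. The 11 genes of T cells and intraepithelial lymphocytes had a mean of -0.17 ± 0.18 (camera adjusted p = 0.0719), with the granzyme Gzmb at -0.38 ± 0.21 and the integrin Itgae at -0.34 ± 0.19 (Gzmb at -0.20 without knockout replicate 4, Itgae at -0.22 without wild type replicate 1). That list passed without knockout replicate 2 (mean -0.29, camera adjusted p = 0.000413), without wild type replicate 3 (-0.24, 0.0158) and with no filter on signal (-0.16, 0.00666). Without knockout replicate 4 its mean was -0.04. The 16 genes of macrophages, dendritic cells and mast cells (mean -0.06 ± 0.07, camera adjusted p = 0.281) included the lysozyme Lyz2 at -0.39 ± 0.16 and the mannose receptor Mrc1 at -0.32 ± 0.15. Lyz2 was at -0.22 without knockout replicate 4 and Mrc1 at -0.20 without knockout replicate 2. The mean of these 16 genes was -0.12 without knockout replicate 1 and -0.03 without knockout replicate 5. Of 24 genes of antigen presentation and interferon response 16 were higher (mean 0.11 ± 0.11; adjusted p = 0.183), with the immunoproteasome subunit Psmb10 at 0.20 ± 0.09 and B2m at -0.24 ± 0.13. This list passed without knockout replicate 4 (adjusted p = 0.048), while without knockout replicate 2 the mean was 0.04.

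Smooth muscle markers were higher on the arrays labelled knockout, 13 of 15, with a mean log2 difference of 0.26 ± 0.16 (SE over arrays; median 0.21). The camera adjusted p was 0.00134 with a preset correlation, and the adjusted p was 0.567 with an estimated correlation. Des (desmin; 0.75 ± 0.21) and Smtn (smoothelin; 0.55 ± 0.17) passed when adjusted over the list alone (adjusted p = 0.0405 for both). Tpm2, a tropomyosin, and Myh11, the smooth muscle myosin heavy chain, differed by 0.49 ± 0.18 and 0.48 ± 0.20. The list differed by 0.35, 0.16 and 0.27 within runs 1, 2 and 3 but by -0.084 within module 4, and it no longer passed without wild type replicate 1 (mean 0.15; adjusted p = 0.0519) or without both arrays labelled replicate 1 (mean 0.10; adjusted p = 0.271). Adipose tissue genes were higher too, 6 of 7, by 0.59 ± 0.32 (median 0.52; camera adjusted p = 0.00734; adjusted p = 0.54 with an estimated correlation). Retn, Cidec, Car3 and Adipoq, genes typical of fat cells, differed by 0.62 ± 0.21, 0.52 ± 0.23, 1.31 ± 0.59 and 1.05 ± 0.54, and none passed over the list alone. Cidec differed by 0.32 without wild type replicate 3, and Adipoq by 0.67 and 1.59 without wild type replicates 1 and 2. The adipose list differed by 0.15, 0.65 and 1.34 within the runs and by 0.41 within module 4. It did not pass without knockout replicate 5 (adjusted p = 0.0639) or wild type replicate 3 (0.069), or with the filter at the 60th percentile (0.108), with means of 0.46, 0.44 and 0.49.

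Endothelial markers were lower for 9 of 10 genes (mean -0.14 ± 0.06 SE, median -0.10; camera adjusted p = 0.0416; adjusted p = 0.54 with an estimated correlation). Kdr, a receptor for vascular endothelial growth factor, and Emcn (endomucin) differed by -0.32 ± 0.12 and -0.31 ± 0.14, and Cdh5 and Pecam1, of endothelial junctions, by -0.28 ± 0.16 and -0.17 ± 0.12. Differences within the 3 runs were -0.15, -0.03 and -0.34, and -0.33 within module 4. The call ended without knockout replicate 2 or 5 or wild type replicate 2 or 5 (adjusted p = 0.0873, 0.0879, 0.128 and 0.0711), with means of -0.12, -0.10, -0.11 and -0.13 that stayed near the full one. It also ended with quantile normalization (mean -0.12; adjusted p = 0.101), cyclic loess (-0.12; 0.0793) and the mean over each gene's probe sets (-0.11; 0.0524). Fibroblast and matrix genes (19 measured, mean 0.07 ± 0.12; adjusted p = 0.285) did not pass, with Col6a2, a collagen, at 0.29 ± 0.15 and Vim (vimentin) at 0.33 ± 0.18, but did so without knockout replicate 2 (adjusted p = 0.0242) and, as lower and on 1 knockout array, with the module as a block (mean -0.23; adjusted p = 0.0294). Enteric neuron and glia genes were 5 higher and 5 lower (mean 0.04 ± 0.12; adjusted p = 0.599), with the neuronal genes Stmn2 and Uchl1 at 0.31 ± 0.14 and 0.28 ± 0.16. With the module as a block, where only 1 knockout array informs a value, this list passed as lower (mean -0.47; adjusted p = 8.74e-05).

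Absorptive enterocyte genes were lower for 19 of 26, by a small mean of -0.09 ± 0.14 (SE over arrays; median -0.14). The camera adjusted p was 0.0311 with a preset correlation, and the adjusted p was 0.623 with an estimated correlation. The brush border peptidases Enpep and Mme differed by -0.34 ± 0.11 and -0.27 ± 0.11 and apolipoprotein Apob by -0.34 ± 0.18, while the fructose transporter Slc2a5 differed by 0.42 ± 0.13. Within the 3 runs the list differed by 0.0027, 0.025 and -0.49 and within module 4 by -0.28. Without knockout replicate 3 or 5, or wild type replicate 1, 2 or 5, the call ended (adjusted p = 0.355, 0.114, 0.131, 0.143 and 0.312), as it did with quantile normalization (mean -0.04; 0.106) and the mean over each gene's probe sets (mean -0.11; 0.0547). The mean was -0.15, -0.02 and -0.05 without knockout replicates 1, 3 and 5 and -0.07, -0.06, -0.18 and -0.03 without wild type replicates 1, 2, 3 and 5. Goblet cell genes were lower for 10 of 13 (mean -0.10 ± 0.10; adjusted p = 0.069), with the mucin Muc13 at -0.37 ± 0.13 and the goblet cell factor Spdef at -0.22 ± 0.12. That list passed without knockout replicate 1 or 4 or wild type replicate 4 (means -0.16, -0.13 and -0.14, camera adjusted p = 0.00288, 0.048 and 0.0144). It also passed without both arrays labelled replicate 1 (-0.17, 0.00635) and with array weights (-0.11, 0.0408). Without knockout replicate 3 its mean was -0.03.

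Of 9 Paneth cell genes 7 were lower and 2 higher. Their median was -0.14 and camera gave them as lower (adjusted p = 0.198), but their mean was 0.21 ± 0.29, set by the alpha-defensin Defa31 at 2.86 ± 1.91 on a probe set that may read several defensins. Over left-out arrays Defa31 ranged from 1.97 to 4.46 and the list mean from 0.10 to 0.39, and over all settings they reached 7.26 and 0.82 with the module as a block, as Defa31 was near the floor on several arrays. The matrix metalloproteinase Mmp7 differed by -0.31 ± 0.15. Enteroendocrine genes (16 measured, mean 0.03 ± 0.08; adjusted p = 0.616) had the neurotensin gene Nts at -0.30 ± 0.21 and the prohormone convertase Pcsk1 at 0.19 ± 0.14. Tuft cell genes had 4 measured members, too few for the test, with Trpm5, a taste channel, at 0.12 ± 0.11 and Alox5ap at -0.10 ± 0.12.

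Genes along the length of the small intestine did not pass the threshold as lists, which does not exclude a difference. The 12 proximal genes had a mean of -0.07 ± 0.15 (camera adjusted p = 0.324) and the 12 distal genes -0.09 ± 0.15 (adjusted p = 0.281). The proximal list passed without wild type replicate 3 (adjusted p = 0.0230), while without knockout replicate 3 its mean was -0.0038. Slc40a1, the iron exporter ferroportin, differed by -0.61 ± 0.16 and passed adjusted over the proximal list alone (adjusted p = 0.0220), and the hormone gene Cck differed by 0.14 ± 0.11. The mean of the distal list was -0.20 without knockout replicate 1 and -0.04 without wild type replicate 3. Among distal genes Nts and the metalloprotease Mep1b differed by -0.30 ± 0.21 and -0.21 ± 0.15. Exocrine pancreas genes (8 measured, mean -0.06 ± 0.08, median 0.0034; adjusted p = 0.734) included Cela1 at 0.27 ± 0.11 and Prss2 at -0.44 ± 0.18. None of the erythroid genes was bright enough to be tested. With an estimated correlation no list of any kind passed, and the lowest adjusted p was 0.54, and none passed by exact permutation of list means (lowest adjusted p = 0.492).

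Dbp, an output gene of the circadian clock, was 2.07 times as high on the arrays labelled knockout (log2 1.05 ± 0.28 SE; adjusted p = 0.441), and it alone of 13 clock genes passed when adjusted over the list alone (adjusted p = 0.0310). Bhlhe40, a repressor in the clock, differed by 0.42 ± 0.18. The clock list had a mean of 0.19 ± 0.10 with 11 genes higher (camera adjusted p = 0.149). Without knockout replicate 5 the list passed (adjusted p = 0.00284) and so did Dbp over all probe sets (log2 1.34; adjusted p = 0.0434). Within runs 1, 2 and 3 Dbp differed by 1.08, 1.70 and -0.33, and within module 4 by -0.29. The values of run 3 and module 4 both rest on knockout replicate 5, on which Dbp was low.

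Among 17 glucocorticoid and thyroid hormone responsive genes 12 were higher (mean 0.11 ± 0.12; camera adjusted p = 0.247). Nr3c1, the glucocorticoid receptor, was lower by a log2 difference of -0.42 ± 0.11 and passed adjusted over the list alone (adjusted p = 0.0299), while its target Tsc22d3 differed by 0.39 ± 0.14. In the family of Klf9, 14 KLF and Sp factors had a mean of -0.05 ± 0.05 (camera adjusted p = 0.183). Sp3 differed by -0.50 ± 0.14 and passed over the list alone (adjusted p = 0.0424), and Sp1 differed by -0.24 ± 0.11.

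Of 19 genes of fatty acid oxidation and PPAR alpha targets 15 were higher (mean 0.10 ± 0.07; camera adjusted p = 0.069), with the lipid droplet gene Plin2 at 0.35 ± 0.10 and the carnitine palmitoyltransferase Cpt2 at 0.29 ± 0.12. The list passed without knockout replicate 3 or wild type replicate 1 or 2 (adjusted p = 0.0162, 0.0266 and 0.0458). Cholesterol synthesis genes were lower for 13 of 18 (mean -0.07 ± 0.11; adjusted p = 0.179), with Dhcr7 at -0.20 ± 0.11 and Nsdhl at -0.18 ± 0.15, and passed without knockout replicate 5 (adjusted p = 0.0201), wild type replicate 1 (0.0332) or both arrays labelled replicate 1 (0.049), while without wild type replicate 3 the mean was -0.02. As higher it passed with the module as a block (mean 0.18; adjusted p = 0.0294), a call that rests on 1 knockout array. Xenobiotic metabolism genes (27 measured, mean 0.09 ± 0.19; adjusted p = 0.331) included the cytochrome Cyp2c29 at 0.62 ± 0.33 and the glutathione transferase Gstm1 at 0.38 ± 0.21 (Cyp2c29 at 0.33 without knockout replicate 4, Gstm1 at 0.24 without knockout replicate 1), and passed without knockout replicate 3 (adjusted p = 0.00247). Immediate early and heat shock genes were higher for 13 of 17 (mean 0.14 ± 0.09; adjusted p = 0.127), with Hspa1b at 0.74 ± 0.34 and Ccn1 at 0.21 ± 0.13, and passed without knockout replicate 3 (adjusted p = 0.0303), wild type replicate 1 (0.0258) or both arrays labelled replicate 1 (0.049). Endoplasmic reticulum stress genes were 9 higher and 10 lower (mean -0.05 ± 0.08; adjusted p = 0.247), with the transcription factor Xbp1 at -0.27 ± 0.11 and Asns at -0.42 ± 0.21.

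**Figure D3:**
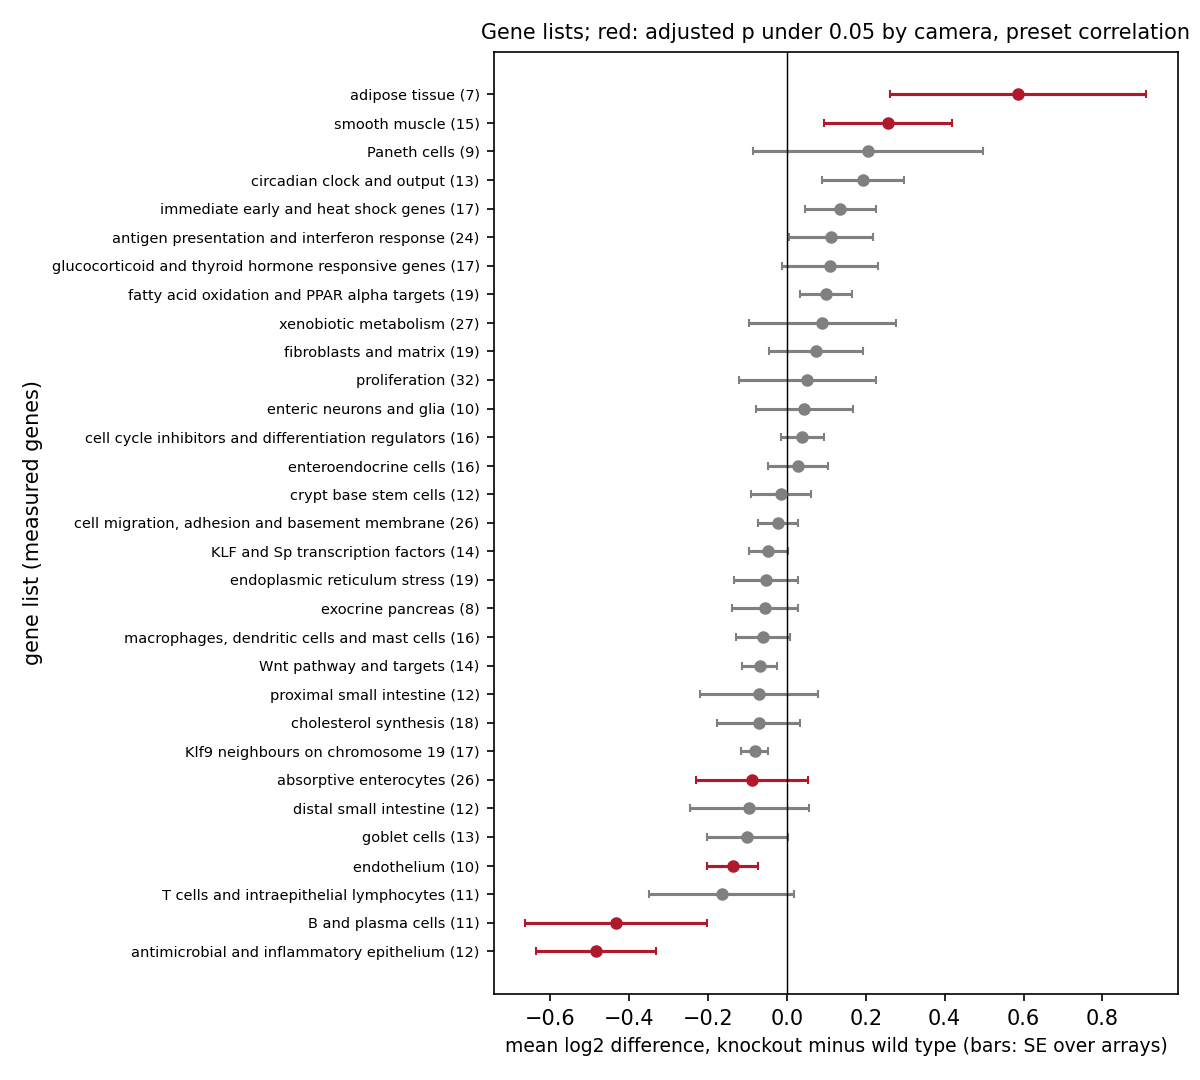
Mean log2 difference of each tested gene list, arrays labelled knockout minus wild type (horizontal axis), with the SE over arrays; the number of measured genes follows each list's name, and red points had a camera adjusted p under 0.05 with a preset correlation. Adipose tissue (0.59) and smooth muscle (0.26) lie to the right, and antimicrobial (-0.48) and B cell genes (-0.43) to the left, none of which passed with an estimated correlation.

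Klf9 lies on chromosome 19, where sequence from the strain of the targeted cells can remain around a mutated gene. No probe set passed there or elsewhere. At an unadjusted p under 0.05, a threshold chosen after seeing that count, 38 of 468 probe sets on chromosome 19 (8.12%) and 939 of 11983 on other chromosomes (7.84%) differed, a two-sided Fisher's exact p of 0.793. Within 20 Mb of Klf9 the count was 35 of 362 (9.67%), against 7.79% outside (Fisher's exact p = 0.196). A list of neighbours of Klf9 had been fixed by gene names and not by mapped positions. Its 17 measured genes had a mean of -0.08 ± 0.03 (camera adjusted p = 0.104), with Gda at -0.31 ± 0.14 and Gnaq at -0.30 ± 0.14. That list passed with the mean over each gene's probe sets, where its mean moved to -0.21 (camera adjusted p = 0.0107).

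The animals were male per the series' design text, with no female array in the comparison to set a background for the sex-linked genes. The Y-linked gene Eif2s3y ranged from 209 to 451 over the 10 arrays and Kdm5d from 185 to 298 on its brightest probe set, from 79 to 143 and from 6.5 to 67.4 on its others. Uty ranged from 101 to 238 over its 2 probe sets. Xist, expressed from the inactive X chromosome of females, ranged from 3.5 to 48.8 and from 4.8 to 24.2 on 2 probe sets and from 116 to 288 on another. No measure of RNA quality differed clearly between the groups at n = 5. Means and SDs of these measures are linear, and their permutation tests were run on log2 values. The 18S signal was 6437 ± 3632 on the arrays labelled knockout and 8654 ± 6574 on those labelled wild type (SD, n = 5, exact permutation p = 0.627). The ratio of 3' to 5' signal of Actb was 1.17 ± 0.07 on the arrays labelled knockout and 1.14 ± 0.05 on those labelled wild type (SD, n = 5; exact permutation p = 0.452), and that of Gapdh was 1.02 ± 0.07 and 0.97 ± 0.10 (SD, n = 5; exact permutation p = 0.421).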

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

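In this part the counts over the 100 drawn splits of all 10 arrays, the wash run block and the leaving out of single arrays were planned, and these tests were chosen after the results were seen: exchanged labels, hormone response, clock phase, muscle share, the use of 1 left-out array to explain a list, the splits of 8 arrays, the left-out pairs and the splits balanced over wash runs. Several criteria were also altered after a first result. The count over splits of 8 arrays first included Klf9 (9 probe sets), and the arrays left out were picked for their Klf9 level. Muscle share was first tested for both lists together without a decision, then for each list, and then without 2 genes. The bound for the single low array was widened from 1 to 2 SE, and at 1 SE the test would have decided against a single array. Of 274 sets of 5 arrays examined, 10 held an array far from its group, where chance gives about 1 in 20.

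Dim Klf9 probe sets had a high array among those labelled wild type, replicate 5 on one (log2 7.42, the others 6.80 to 6.90) and replicate 3 on another (7.28, the others 6.85 to 6.95). Zfp36l1 was high on knockout replicate 5 (9.78, the others 9.46 to 9.55), and Spdef on wild type replicate 2 (8.94, the others 8.38 to 8.52). Tcf7l2 was low on knockout replicate 1 (7.89, the others 8.38 to 8.49) and on wild type replicate 2 (8.41, the others 8.62 to 8.69). Defa31 was low on knockout replicate 2 (5.95, the others 13.4 to 14.8).

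The list of antimicrobial and inflammatory epithelium was low on knockout replicate 3 (9.71, the others 10.2 to 10.4), which also had the lowest B and plasma cell score (8.33) and the lowest 18S signal (538). A larger share of muscle layer in the knockout samples would lower mucosal lists together: the antimicrobial list lay below absorptive enterocytes by -0.40 ± 0.17 (SE) on the log2 scale with an upper 95% bound of -0.013, but without Saa1 and Nos2, whose knockout signals (88.4 and 78.3) lie below the filter's 123, by -0.11 ± 0.12 with a bound of 0.16, so that share stays open. For the B and plasma cell list the bound was 0.20, and muscle share stays open there too. Without knockout replicate 3 that list differed by -0.26 ± 0.18 (SE), too close to 0 to settle whether 1 array carries it. Lists past the preset threshold numbered 6, and 67 of 100 drawn splits of the 10 arrays (of 126 possible), the real one included, gave as many, up to 14, so chance is not excluded and genotype stays open.

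Klf9 on the arrays labelled replicate 1 went against both labels. If the labels of these 2 arrays had been exchanged, other genes should place them on the opposite sides. On a score of the 100 probe sets of lowest p on the other 8 arrays, without Klf9, the array labelled knockout lay above the array labelled wild type by 0.028. The 16 held-out pairs of the other arrays gave a mean of 0.50 and an SD of 0.36. These pairs share arrays, so that the SD is not over independent units. Their scores were also built with both arrays labelled replicate 1 under their labels. An exchange cannot be told apart from correct labels with a weak genotype signal. Scores that leave out knockout replicate 1 with wild type replicates 2 to 5 gave -0.52, -0.52, -0.024 and 0.12, and wild type replicate 1 with knockout replicates 2 to 5 -0.0013, 0.018, 0.28 and 0.053, although each of these was built with the other array in question under its label. A shared hormone response is also open: deviations of Klf9 and of the glucocorticoid and thyroid list from their group means had Pearson r = 0.41 (permutation p = 0.239) and Spearman rho = 0.43 (p = 0.217) over 10 arrays, and r = 0.41 without the 2 farthest.

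Without both arrays 8 probe sets other than Klf9 passed, and 1 of 35 splits of the remaining 8 arrays, the real one, gave as many (highest other 6). By the count at an unadjusted p under 0.05, 3 of the 35 splits gave as many as the real 1383, up to 1504. Leaving out any of the 24 other pairs of 1 knockout and 1 wild type array gave at most 3 (median 0). The measures over splits differ, so chance stays open for these arrays, which were picked after their Klf9 values were seen.

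Dbp was low on knockout replicate 5 (8.06, the others 9.29 to 9.74), as was the whole clock list (8.36, the others 8.81 to 8.91). A candidate explanation is that arrays differ in clock phase, as from the hour of collection. Deviations of Dbp, Tef and the Per and Nr1d genes from their group means ran against those of Arntl, Clock and Npas2 over the 10 arrays, with Pearson r = -0.76 (permutation p = 0.00946, adjusted p = 0.0189 over 2 relations) and Spearman rho = -0.73 (p = 0.0204). Without the 2 farthest arrays r was -0.47, so the relation rests partly on them. This goes with a difference in phase between arrays, and leaves open whether phase or genotype set the mean difference of Dbp.

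For the whole comparison, 1072 probe sets had an unadjusted p under 0.05, and 15 of 100 drawn splits, the real one included, gave as many, up to 1830, so chance is not excluded. One of the 14 others parted wash runs 1 and 2 and gave 1664, and with the wash run as a block the real labels gave 1095. Over all 36 splits that keep the balance of the labels over the wash runs, 4 gave as many probe sets as the real 1072, up to 1467, and 24 as many lists as the real 6, up to 12, so chance is not excluded there either.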

How the results depend on the processing

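In this part leaving out both arrays labelled replicate 1, and the rule that a list turns with the sign of its mean, were chosen after the results were seen. The count of 0 passing probe sets held under every alternative that used all 10 arrays except array weights, where 3 passed, and it ranged from 0 to 9 over left-out arrays, the highest without both arrays labelled replicate 1. The count at an unadjusted p under 0.05 was 1072, against 1624 with no filter, where more probe sets were tested, and 471 with the module as a block, where only 3 arrays inform the comparison. The brightest Klf9 probe set kept its direction throughout, with -1.26 to -0.72 over left-out arrays. It passed only without both arrays labelled replicate 1 (-1.26, adjusted p = 0.0147, over all alternatives 0.0147 to 0.999). The number of lists past the threshold, 6, was 4 to 8 under other settings, but 0 with an estimated correlation. Replicate numbers are not taken as pairs, since the labels do not say that they mark a shared litter, day or batch. Correlations of same-numbered deviations were 0.18, 0.03, 0.28, 0.12 and -0.12. Some shared variation is left open, as same-numbered arrays shared a wash run and 3 of 5 arrays of each label correlated best with their own number. With the replicate block 0 probe sets passed, 1232 had an unadjusted p under 0.05 and 6 lists passed.

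Of 2354 values of 95 named genes under alternatives, 2331 kept direction and side of the threshold, 6 passed that had not and 17 turned, all with the module as a block. Of 834 values of lists, 755 kept both, 26 lost the call, 25 gained one and 28 turned. With the module as a block the turned genes were Iglv1 0.078, Slc2a5 -0.088, Cdh5 0.10, Hspa1b -0.50, Dbp -0.29, Bhlhe40 -0.021, Dhcr7 0.070, Nsdhl 0.12, Fzd7 0.028, Mmp7 0.012, Lyz2 0.081, Col6a2 -0.19, Cck -0.0040, Cyp2c29 -0.24, Stmn2 -0.22, Uchl1 -0.39 and Prss2 0.011. The turned lists there were cell cycle inhibitors and differentiation regulators -0.063, enteroendocrine cells -0.16, circadian clock -0.23, glucocorticoid and thyroid -0.30, cholesterol synthesis 0.18, fatty acid oxidation -0.010, xenobiotic metabolism -0.14, antigen presentation -0.040, immediate early and heat shock -0.041, smooth muscle -0.084, fibroblasts and matrix -0.23 and enteric neurons and glia -0.47, all resting on 1 knockout and 2 wild type arrays, with cholesterol synthesis, fibroblasts and neurons past the threshold there. With the mean over probe sets, cell cycle inhibitors gave -0.051 and enteric neurons and glia -0.0017, and with no filter enteroendocrine cells gave -0.0048 and KLF and Sp factors 0.0012. Over left-out arrays the ranges of lists that turned were -0.0072 to 0.061 for cell cycle inhibitors, -0.049 to 0.025 for crypt base stem cells, -0.085 to 0.0017 for endoplasmic reticulum stress, -0.012 to 0.14 for enteric neurons and glia, -0.018 to 0.080 for enteroendocrine cells, -0.071 to 0.15 for proliferation and -0.00062 to 0.23 for xenobiotic metabolism. The cause was not tested. Scaling moved the median of all probe sets by under 0.01, and the offset of 50 understates the fold changes of genes near it. Leaving out 1 array turned the direction of, or moved by over 1.5 times, 28 of 95 named genes and 25 of 31 lists.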

Other observations

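Several genes outside the naming rule, chosen after their values were seen, moved alike on all of their tested probe sets. Stom, which encodes the membrane protein stomatin, was lower on the arrays labelled knockout on 5 of 5 probe sets, from -0.51 ± 0.16 (SE) on the brightest to -1.15 ± 0.24. Ceacam1, an adhesion molecule of the epithelial surface, was lower on 7 of 7, from -0.27 ± 0.13 to -0.81 ± 0.18, with some of these probe sets open to signal from Ceacam2. Ccnd2, a D-type cyclin of the G1 phase, was higher on 5 of 5, from 0.34 ± 0.12 to 0.70 ± 0.12. With limma over all 10 arrays none of these probe sets passed, and the smallest adjusted p was 0.226 (Ccnd2).

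The Defa31 probe set was high or near the floor on single arrays of both labels. Its log2 values were 14.8, 5.95, 13.4, 14.2 and 13.4 on knockout replicates 1 to 5 and 14.3, 6.41, 14.0, 5.92 and 6.91 on wild type replicates 1 to 5. The signal of the prokaryotic cre hybridization control, added at a fixed amount per array, was 27696 and 32194 on wild type replicates 2 and 5 and between 15396 and 21310 on the other arrays. Its mean was 17633 ± 1303 on the arrays labelled knockout and 23246 ± 6589 on those labelled wild type (SD, n = 5, exact permutation p = 0.0873 on log2 values).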
